A study of Glycine max with 20 samples.

How the data were processed

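Small RNAs were sequenced from stem hypocotyls of 10 soybean lines grown in a greenhouse, each after mock inoculation and after standard hypocotyl inoculation, with 1 library per line and treatment. Per the labels' protocols, RNA was taken with the Qiagen miRNeasy Mini kit and libraries were made with the TruSeq Small RNA kit. The authors deposited 1 table of distinct sequences in RPM, the reads of a sequence scaled to all reads of its library, which the file name calls TPM. Bowtie is named, with no version or role, per the submitters' processing notes. Adapter trimming, filters and a genome build are not stated. The columns carry a line and the letter W or R, which were read as mock (water) and inoculated (race). The labels do not spell the letters out, so this reading is a limit of every direction given.

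In all 20 columns the values of up to 200 reads were whole multiples of what 1 read is worth, with 100% of them within 0.1 of a whole read. Reads of the inoculated Williams column, whose step of 0.101 RPM lies close to 0.1, were not used in the count test, a choice made before any test was run, so that test covers the 9 Rps lines. Depth was 3456236 to 6254293 reads in mock libraries and 6801326 to 9897338 in inoculated libraries. Same-treatment pairs of the libraries of the 9 Rps lines differed by 1.46 to 20.9 times counting noise (72 pairs, ratio of median chi-square).

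Sequences of 18 to 30 nt with a mean of at least 10 RPM over all 20 libraries were tested (3843). Families were sums of exact mature sequences from 7 lists fixed before the data were examined, with 44 families and 126 sequences, written from general knowledge. Of these sequences 101 were found, in 43 families, and 33 families had a mean of at least 1 RPM. The soybean gene table (Glycine_max_v4.0), used for names alone, had a microRNA gene symbol for 41 of 43 microRNA families. Values were log2(value + 1). The main test was limma (lmFit and eBayes with trend) with line and treatment as terms, Benjamini-Hochberg adjustment and a threshold of 0.05. Lists with at least 3 families were tested with fry, length classes with an exact two-sided sign-flip permutation test of the 10 within-line differences, line differences with limma's F test, and Williams against the 9 lines with limma on within-line differences or line means. Named items followed a rule set beforehand: every trigger family, up to 12 other families that passed each way by size of change, up to 5 list sequences each way that moved alike in at least 9 lines, and families that passed the line or Williams test.

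The line pairs the libraries by design. As a check, deviations of the 2 libraries of a line from their treatment means had correlations from -0.26 to 0.36 across sequences, and 2 of 10 were over 0.1.

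Alternatives were pseudocounts of 0.5 and 5, filters of 5 and 50 RPM or none for families, rescaling by the median ratio or to the total of 20 to 24 nt reads, no trend, no line term, isomiRs that hold positions 2 to 18, edgeR's quasi-likelihood test on the recovered reads of the 9 Rps lines, each line left out, and length classes as a percent of 20 to 24 nt reads or by distinct sequences. Division by the median family level (the median RPM of the tested families in each library, which is not the same family in every library), division by the median level of the 27 families of mean at least 10 RPM with these tested, leaving out rRNA pieces, and leaving out Rps1-c and Rps3-a together were added after the data were seen. rRNA pieces were exact matches of at least 18 nt to stretches of plant 18S and 25S rRNA written from memory.

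The limma and edgeR tests were tested on simulated data with 200 of 3843 sequences changed. The inoculation test recovered 59.7% of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold changes, and called 0.19% of unchanged sequences. For edgeR on 9 lines the recovered shares were 58.2%, 95.5% and 100%. The simulated data held no shift in library composition. The recovered shares and the 0.19% therefore do not carry over to data with such a shift. Reads over NB-LRR genes and phased loci were not analysed here, since they need a soybean genome, which was not used here. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.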

Results

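Small RNA reads were counted in stem hypocotyls of soybean after mock inoculation or inoculation with Phytophthora sojae, the oomycete that causes root and stem rot. There were 10 lines, the susceptible parent Williams and 9 near-isogenic lines with an Rps resistance gene (Rps1-a, Rps1-c, Rps1-k, Rps3-a, Rps3-b, Rps3-c, Rps4, Rps5 and Rps6). Each line gave 1 mock and 1 inoculated library, so the lines are the replicates of the treatment (n = 10 per treatment) and no line has a replicate of its own. The table listed 10712380 distinct sequences of 17 to 98 nt in RPM, the reads of a sequence scaled to all reads of its library. The values implied 3456236 to 6254293 reads in the mock libraries, 6801326 to 9523462 in the inoculated libraries of the 9 Rps lines and 9897338 in the inoculated Williams library, so that depth separated the treatments completely. The column letters W and R were read as mock (water) and inoculated (race), which the labels do not spell out, and the opposite reading would reverse every direction given here.

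The first question was how the classes of small RNA changed with inoculation. Reads of 21 nt, the length of most microRNAs and phased siRNAs, made up 26.6% ± 1.79 (SD, n = 10) of mock libraries and 14.1% ± 1.56 of inoculated libraries. Reads of 22 nt, the length of microRNAs that start phased siRNAs, fell from 12.0% ± 0.98 to 7.31% ± 0.90. Reads of 24 nt, the length of heterochromatic siRNAs, fell from 15.3% ± 2.05 to 8.50% ± 1.19. The classes of 18 to 20 nt and of 25 to 30 nt all took a larger share of reads after inoculation, such as 27 nt reads with 1.37% ± 0.16 in mock and 3.50% ± 0.52 in inoculated libraries. These 12 classes moved the same way in 10 of 10 lines (exact two-sided sign-flip permutation test, p = 0.00195, the smallest that 1024 flips can give, adjusted p = 0.0021 over 13 classes). By distinct sequences the 25 nt class did not pass (0.0819 points, exact permutation, adjusted p = 0.107) and the 23 nt class was lower (-0.332 points, adjusted p = 0.0381). In reads the 23 nt class was 2.88% ± 0.12 in mock and 2.96% ± 0.16 in inoculated libraries (exact permutation p = 0.289). As a percent of the 20 to 24 nt reads alone, the 23 nt class was higher after inoculation by 3.58 points and the 20 nt class by 2.86 points, each in 10 of 10 lines (exact permutation, adjusted p = 0.0033). On that basis 21 nt reads were lower by a smaller margin (45.4% against 40.4%), the 22 nt difference turned to 0.408 points higher (adjusted p = 0.203), and the 24 nt difference of -1.81 points did not pass (exact permutation, adjusted p = 0.0659).

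**Figure D1:**
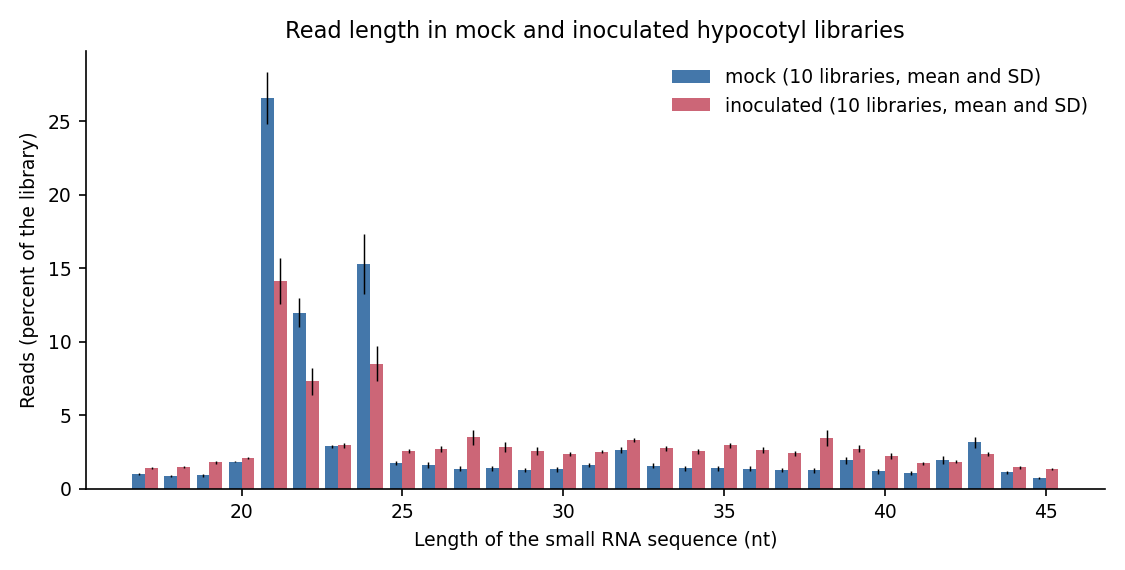
Percent of reads of each length from 17 to 45 nt (x axis, nt) in 10 mock and 10 inoculated libraries, with bars for the mean and lines for the SD. The 21, 22 and 24 nt classes were lower in inoculated libraries, with 21 nt reads at 14.1% against 26.6%.

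Reads outside the small RNA lengths grew in share. Reads of 20 to 24 nt were 58.6% ± 4.02 of mock and 35.0% ± 3.67 of inoculated libraries, while reads over 24 nt were 38.6% ± 3.78 and 60.3% ± 3.63. Pieces that matched a 279 nt stretch of plant 18S rRNA rose from 0.397% ± 0.223 to 2.78% ± 0.799 of reads, and pieces of a 1045 nt stretch of 25S rRNA rose from 3.16% ± 0.423 to 7.30% ± 0.420. Each of these shares moved the same way in 10 of 10 lines (exact sign-flip permutation p = 0.00195). Both stretches were chosen after the data were seen and cover part of each rRNA. An exact match to them would also count an identical piece of oomycete rRNA.

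The second question was which microRNA families changed. Of 33 families tested, 31 fell in RPM with inoculation and 0 rose (limma, adjusted p under 0.05). miR398, a family that targets copper proteins, fell by 1.99 ± 0.19 (SE) on the log2(value + 1) scale, from 38.4 ± 33.9 (SD) to 8.42 ± 5.04 RPM (adjusted p = 7.928e-08, lower in 10 of 10 lines). miR166, which targets HD-ZIP III transcription factors and was the most abundant family here, went from 163946 ± 15730 to 78295 ± 9518 RPM. Its log2 difference was -1.07 in RPM, -0.32 after rescaling to the 20 to 24 nt reads (adjusted p = 2.434e-06) and -0.10 after division by the median family level of each library, where it did not pass (adjusted p = 0.309). Relative to the median level of the 27 families of mean at least 10 RPM it rose (0.22, adjusted p = 0.0216). Of these 27 families 8 rose and 3 fell relative to that level, and the 3 were miR398, miR399 and tasiARF. The 2 families that did not pass were miR862 (log2 difference 0.14, adjusted p = 0.493) and miR1512 (-0.20, adjusted p = 0.360), for which 5 of 10 lines shared the direction. After rescaling to the 20 to 24 nt reads miR862 (0.48, adjusted p = 0.0270) and miR1512 (0.41, adjusted p = 0.0343) rose. After division by the median family level they also rose (0.61, adjusted p = 0.0168, and 0.59, adjusted p = 0.0089). The log2 scale with a pseudocount understates changes of low families.

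All 5 families of the trigger list, which target transcripts of NB-LRR resistance genes and start phased siRNAs from them, fell. miR2118 fell by 1.39 ± 0.12, miR482 by 1.28 ± 0.10, miR2109 by 1.15 ± 0.17, miR1507 by 0.98 ± 0.12 and miR1510 by 0.62 ± 0.10 on the log2 scale, each lower in 10 of 10 lines. miR1507 was the most abundant of them, with 30846 ± 4365 RPM in mock and 15790 ± 3331 in inoculated libraries. The values of miR1510 and miR2109 came almost wholly from 21 nt sequences (means of 387.5 and 20.23 RPM), with 0.232 RPM for the 22 nt sequence of miR1510. They therefore do not measure a 22 nt form. miR1510 turned direction when values were rescaled to the 20 to 24 nt reads (log2 difference 0.12, adjusted p = 0.209), and rose when divided by the median family level of each library (0.35, adjusted p = 0.0123). After rescaling to the 20 to 24 nt reads 4 of the 5 trigger families fell, and after division by the median family level 2 fell, miR2118 and miR482, while miR1507 (-0.01, adjusted p = 0.911) and miR2109 (-0.24, adjusted p = 0.144) did not pass. Relative to the median level of the 27 families 0 of the 5 fell, miR1507 (0.31, adjusted p = 0.0042) and miR1510 (0.67, adjusted p = 1.068e-05) rose, and miR2118 (-0.10, adjusted p = 0.407), miR482 (0.01, adjusted p = 0.882) and miR2109 (0.07, adjusted p = 0.726) did not pass.

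The 4 families of the silencing list, which target transcripts of the small RNA machinery, all fell in RPM. After rescaling to the 20 to 24 nt reads 3 fell and miR1515 did not pass (log2 difference -0.02, adjusted p = 0.861). After division by the median family level 2 fell, miR1515 turned direction (0.15) and miR403 did not pass (-0.26, adjusted p = 0.0522). The 2 that fell, miR168 (-0.11, adjusted p = 0.594) and miR162 (-0.02, adjusted p = 0.882), did not pass relative to the median level of the 27 families, nor did miR403, which turned direction (0.05). miR168, which targets AGO1, fell by 1.40 ± 0.22 on the log2 scale. miR162, which targets DCL1, fell by 1.30 ± 0.18, and miR403, which targets AGO2, fell by 1.21 ± 0.13. All 5 families of the auxin list fell in RPM. After rescaling to the 20 to 24 nt reads 3 fell, miR390 turned direction (0.04) and miR167 did not pass (-0.24, adjusted p = 0.176). After division by the median family level 2 fell, miR390 rose (0.26, adjusted p = 0.0383), and miR160 (-0.26, adjusted p = 0.109) and miR167 (-0.06, adjusted p = 0.794) did not pass. Of the 2 that fell, tasiARF also fell relative to the median level of the 27 families, where miR393 did not pass (-0.19, adjusted p = 0.135) and miR160 turned direction (0.05). Among the auxin families were tasiARF, which fell by 1.57 ± 0.17, the TIR1/AFB regulator miR393, which fell by 1.46 ± 0.14, and miR160, which fell by 1.20 ± 0.16. All 7 tested families of the development list fell, among them miR164 by 1.47 ± 0.17, miR396 by 1.31 ± 0.14, miR319 by 1.23 ± 0.13 and miR156 by 1.11 ± 0.12. All 7 also fell after rescaling to the 20 to 24 nt reads, and 3 fell after division by the median family level, where 4 did not pass, among them miR156 (-0.14, adjusted p = 0.273) and miR166. Relative to the median level of the 27 families 0 of the 7 fell, miR159 (0.30, adjusted p = 0.011) and miR166 rose, and 5 did not pass, of which miR319 (0.07), miR156 (0.19) and miR171 (0.22) turned direction. Of the nutrient list 2 of 2 tested families fell, and the phosphate family miR399 fell by 1.63 ± 0.18, while miR2111 turned direction after both of these rescalings (0.04 and 0.24). Of the copper list 2 of 2 fell in RPM, where miR408 was at -0.47 (adjusted p = 0.0075). But miR408 turned direction after rescaling to the 20 to 24 nt reads (0.18, adjusted p = 0.209) and rose after division by the median family level (0.37, adjusted p = 0.0365). In RPM it did not pass without Rps1-c and Rps3-a (-0.37, adjusted p = 0.0532) or without the line term (adjusted p = 0.0898). Of the other list 6 of 8 fell in RPM. Of these, miR1511 rose after rescaling to the 20 to 24 nt reads (0.25, adjusted p = 0.0038) and after division by the median family level (0.48, adjusted p = 5.780e-04). Only after division by the median family level did miR1508 turn direction (0.06). In the other list 0 families fell, 3 rose and 5 did not pass after that division, and 0 of 6 fell and 3 rose relative to the median level of the 27 families. The members miR166, miR159, miR171, miR1515, miR167, miR390, miR2111, miR1511 and miR1508 were named after their values were seen. Adjusted over the list alone, the counts were the same in all 7 lists. The 5 lists with at least 3 tested families moved down on balance (fry of limma, adjusted p from 5.449e-06 to 1.282e-05), a test that does not compare a list with other families. After rescaling to the 20 to 24 nt reads the other list did not pass (adjusted p = 0.110), with 3 of its families higher and 3 lower.

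**Figure D2:**
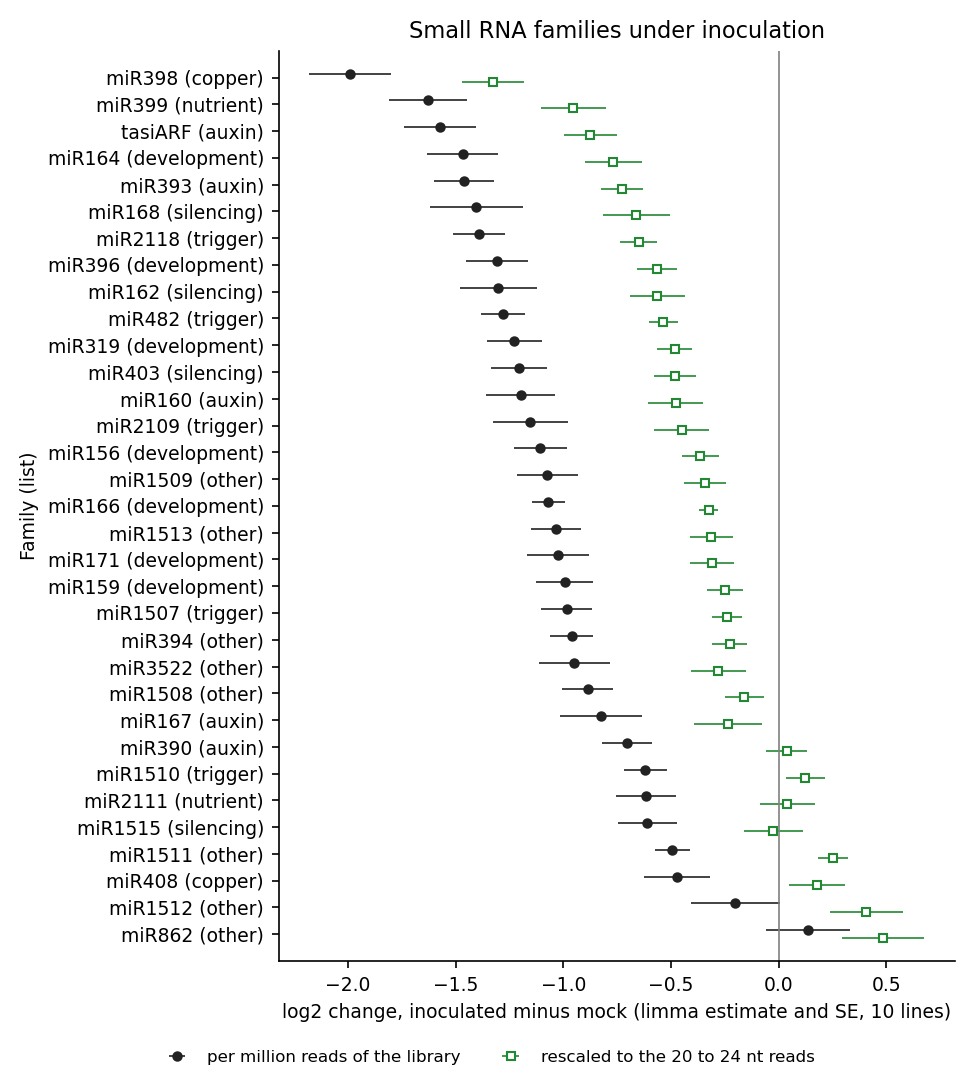
Log2 change of each of 33 families, inoculated minus mock (x axis, log2 of value + 1), as limma's estimate with its SE over 10 lines. Filled points are RPM and open squares are rescaled to the 20 to 24 nt reads, where 22 families fell and 3 rose, and miR1510, miR390, miR2111, miR408, miR1511 and miR1512 were on the other side of 0.

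The scaling set how large the fall was. The median family change was -1.07 on the authors' scaling, -1.36 after rescaling by the median ratio (a shift of -0.29) and -0.32 after rescaling to the 20 to 24 nt reads (a shift of 0.74). Under this last scaling 22 families fell and 3 rose, and of the calls 12% were higher against 0%. Of 49 single mature sequences of the lists that were tested, 47 fell and 1 rose. After rescaling to the 20 to 24 nt reads 34 fell and 4 rose. The 1 that rose was AACCAGGCTCTGATACCATG of miR1511 (0.39 ± 0.15, limma adjusted p = 0.016, higher in 8 of 10 lines), named after its values were seen, since it moved alike in fewer than 9 lines. The 5 that fell most were TGTGTTCTCAGGTCGCCCCTG of miR398 (fell by 1.98 ± 0.18), TGCCAAAGGAGAGTTGCCCTG of miR399 (fell by 1.70 ± 0.18), CCTCATTCCAAACATCATCTAA of miR1507 (fell by 1.61 ± 0.20), TTCTTGACCTTGTAAGACCTT of tasiARF (fell by 1.57 ± 0.16) and TCGGACCAGGCTTCATTCCCG of miR166 (fell by 1.47 ± 0.15), each in 10 of 10 lines.

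Across all distinct sequences of 18 to 30 nt, 3843 had a mean of at least 10 RPM. Of these, 1912 rose and 1659 fell with inoculation, and 272 did not pass (limma, adjusted p under 0.05). Of the 463 sequences of 21 nt 337 fell and 102 rose, and of the 559 of 22 nt 425 fell and 114 rose. After rescaling to the 20 to 24 nt reads, 445 of these 1022 sequences fell and 268 rose, against 762 and 216 in RPM. Among 497 sequences that matched the rRNA stretches, 354 rose and 98 fell, with a median log2 change of 1.77. Of the calls, 53.5% were higher on the authors' scaling, 50% after the median ratio (a shift of the median by -0.27) and 75.4% after rescaling to the 20 to 24 nt reads (a shift of 0.69, 2182 rose and 710 fell). The median ratio was set on 3748 of these same sequences, so its near-even split was built in and is no result. The first principal component, with 91.0% of the variance, separated the treatments.

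The third question was which small RNAs differed between the lines, whatever the treatment. The copper families miR398 (F = 9.16, adjusted p = 0.0025) and miR408 (F = 5.88, adjusted p = 0.0173) and the phosphate family miR399 (F = 4.55, adjusted p = 0.0445) differed between lines in limma's F test. miR398 and miR408 were farthest from the median line in Rps3-c, by -1.84 and -1.06 on the log2 scale. Low values were not limited to Rps3-c. In the inoculated libraries of Rps3-c, Rps4, Rps5 and Rps6 miR398 was at 1.04 to 4.12 RPM, against 7.93 to 15.93 in the other lines. For miR408 these ranges were 3.11 to 5.29 and 7.68 to 11.89, while the mock values of the 2 sets of lines overlapped. The labels give no batch, so a processing group and the lines cannot be told apart. miR399 was farthest in Rps3-a, by 1.30. Rps3-a had the highest mean log2 level of all 3 families, such as 129.9 RPM of miR398 in its mock library, where the median line had 30.9. Its inoculated library had 15.93 RPM of miR398, close to the 13.73 of Rps1-c. For miR408 it had 11.89 RPM, close to the 11.12 of Williams. The high levels of miR398 and miR408 in Rps3-a thus rest mainly on its mock library. Without Rps3-a, 1 family and 2 sequences passed, in place of 3 families and 7 sequences.

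**Figure D3:**
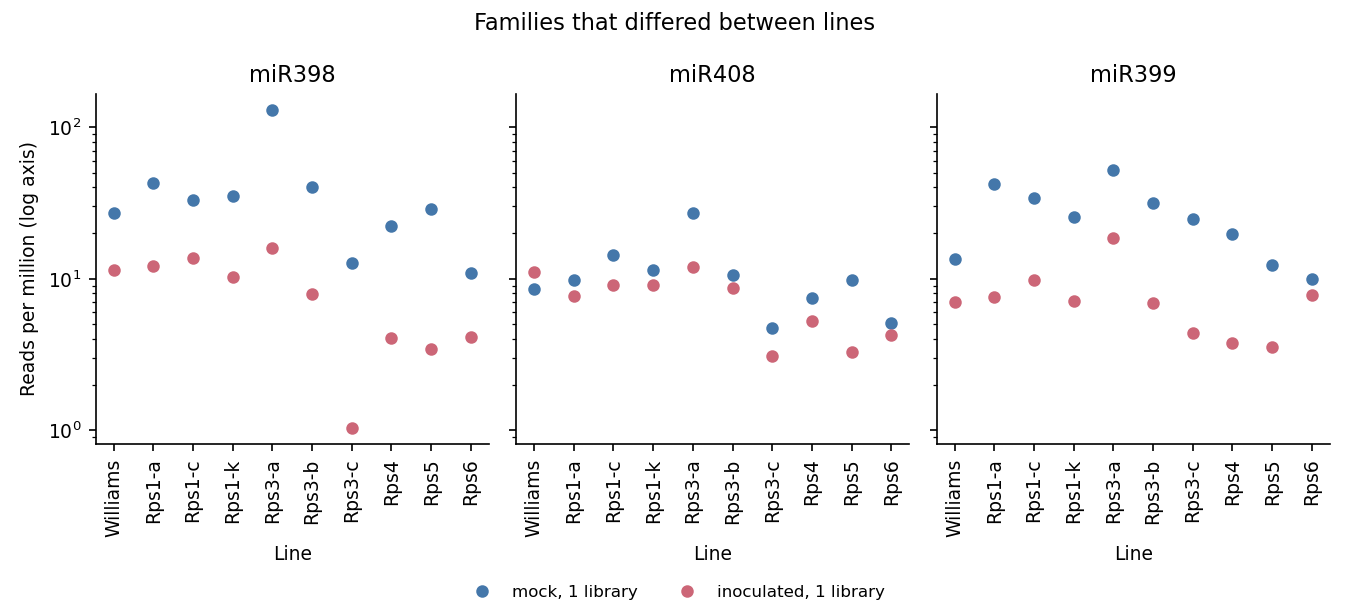
RPM (y axis, log scale) of miR398, miR408 and miR399 in the mock and the inoculated library of each of 10 lines, 1 library per point. Rps3-a had the highest mock value of miR398, at 129.9 RPM.

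The 7 sequences that differed between lines were CTGACAGAAGATAGAGAGCAC, ATCGAGATCAATGGAAGGCTT, the miR398 sequence named above and 4 overlapping pieces of GGGTAGAATCCTTTGCAGACGACTTAAATA, all but the miR398 sequence named after their values were seen. The 28 nt piece was at 518.06 to 930.53 RPM in the mock libraries of Rps3-c, Rps4, Rps5 and Rps6, against 85.35 to 363.22 in the other lines. In the inoculated libraries these ranges were 372.45 to 485.01 and 114.7 to 273.71. These are the lines with low miR398 and miR408 after inoculation. CTGACAGAAGATAGAGAGCAC, a miR156 sequence with 1 more base at its start, was at most 0.62 RPM in both libraries of Rps3-c, Rps4 and Rps6 and at least 7.04 in the other lines (F = 55.7, adjusted p = 2.756e-07). ATCGAGATCAATGGAAGGCTT had 1.74 and 1.39 RPM in the mock and inoculated libraries of Rps3-a. At an unadjusted p under 0.05 there were 229 sequences and 5 families. In simulated data the line test found 4.5% of 2-fold and 66.7% of 4-fold changes of 1 line, so small differences between lines would be missed here.

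The last question was whether Williams, the susceptible parent, differed from the 9 lines. No family passed for its response or its level (limma, 0 and 0 families at adjusted p under 0.05, also 0 and 0 at an unadjusted p under 0.05, smallest p 0.0525 and 0.193). In all families but miR390 the response of Williams lay above the mean response of the 9 lines. Its median family change in RPM was -0.69, within the range of the other lines (-0.64 in Rps6 to -1.74 in Rps3-c). 1 sequence of 23 nt fell by 4.80 on the log2 scale in Williams, with a mean change of -1.98 in the other lines (difference -2.82 ± 0.45, limma adjusted p = 0.0491, 281 sequences at an unadjusted p under 0.05). This call was lost with a pseudocount of 0.5, with either rescaling, with a mean of at least 5 or 50 RPM, and without any one of Rps1-c, Rps3-a, Rps3-b, Rps3-c, Rps4, Rps5 or Rps6 (0 sequences each). For levels, 0 sequences differed (limma, 95 at an unadjusted p under 0.05). Williams is 1 line and was assumed to vary like the other 9, since an exact permutation test of 1 against 9 cannot go below 0.1. In simulated data the response test found 34.8% of 4-fold changes and 3.0% of 2-fold changes.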

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

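The tests of composition, dilution, rRNA breakdown, batch, a swap of 1 line, uneven filtering and a mislabelled pair, and all counts of splits of sequences, families and lists, were chosen after the result was seen. For the tests of composition, dilution and a mislabelled pair, the bounds were also changed after the values were seen, the last to ask for pairs of both libraries. For composition and dilution the first bounds asked for a median below -0.1 in every line and for more than 50% of the families, and under them both tests were undecided, since the highest line was at -0.04 and 40.7% of families changed.

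The first pattern is the fall of 31 microRNA families in RPM. Of 100 splits drawn that swap libraries within lines, 1, the real one, gave as many sequences (3571, highest other 3291). This argues against chance for the count of sequences. For families also 1 split, the real one, gave as many (31, highest other 30). With 33 families tested this count is close to the most there can be, so it decides little. As many lists came from 3 splits (5, highest other 5), the most there can be, so the lists exclude nothing. After thinning to 3456236 reads, 100% of the 31 families that fell in the 9 Rps lines still fell. Thinning keeps the expected RPM of each family, so this speaks only against uneven counting noise. Whatever made depth differ between the treatments stays open. Against the growth of reads outside 20 to 24 nt as the whole cause, the median family lay at -0.34 ± 0.19 (mean and SD of 10 lines) after rescaling to 20 to 24 nt reads, below 0 in 10 lines, and against 1 dilution factor, 40.7% of 27 families (8 higher, 3 lower) changed relative to the median level of these 27, and 17 of 33 (6 higher, 11 lower) relative to that of all 33. Both rest on the changed bounds, which families lie above or below depends on the reference level, the median family moved from -1.07 to -0.32 on that rescaling, rRNA pieces inside that window rose from 1.05% to 3.42% of its reads so that its own dilution stays open, and a response of the plant to inoculation stays open and untested, as does a batch that follows the treatment.

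The second pattern is the larger share of rRNA pieces after inoculation. Breakdown that raises all pieces alike is argued against by the log2 changes of the 497 matching sequences, whose 10th and 90th percentiles lay 5.18 apart. This spread cannot decide on breakdown that raises pieces by different amounts, which was not tested and stays open. The lowest of the 10 within-line log2 ratios of the share was 1.14, and the labels give no batch, so a library batch and the treatment cannot be told apart. Damage of the tissue by the oomycete may also raise these pieces and was not tested. The exact matches also do not tell plant rRNA from identical pieces of oomycete rRNA.

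A swap of the columns of single lines is argued against by 21 nt reads, which were lower in the inoculated library in 10 of 10 lines, but a reversal of the letters in all lines would look the same. A test of the letters with pieces of oomycete 5.8S rRNA was void, since it found 0 RPM in all 20 libraries, and looks at other rRNA stretches decided nothing.

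The third pattern is a set of 1397 sequences of 17 to 87 nt listed at 1 or more RPM in the Rps1-c mock and Rps3-a inoculated libraries and at 0 in the other 18. They held 4.42% and 4.24% of these libraries, and 297 lay inside the rRNA stretches. Uneven filtering by the authors is a candidate explanation, since 94.0% shared 16 nt with a sequence listed in all other 18 libraries. Of 27 sequences listed only in the 2 libraries of a line, 3.70% shared 16 nt with a sequence listed in all 20. A high share cannot single out filtering. Of the sequences in at least 5 inoculated and no mock libraries, 89.1% shared 16 nt with a sequence listed in all mock libraries. Sequences listed only in 2 libraries could not decide on a mislabelled library. The other pairs with at least 2 of them were the 2 libraries of a line (3 of 3). None included the Rps3-a inoculated library. A 21 nt sequence was at 1.74 and 1.39 RPM in the mock and inoculated Rps3-a libraries. It was at 45.16 and 24.61 in those of Rps1-c and at least 7.51 in the other lines. Another 2, of which 1 overlaps it, were at most 0.38 and 0.25 RPM in Rps3-a and at least 2.85 and 3.2 elsewhere. If they follow the line, these values argue against an exchange of libraries between Rps1-c and Rps3-a. They were picked after being seen, and other mislabelling stays open. An animal source was left open, since the listed animal microRNAs summed to 0 RPM in all 20 libraries, and no biological explanation was tested.

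Among 78 groups of 10 libraries checked for a library far from the others, 9 had one, where chance gives about 3.9. The share of the 18S stretch was 1.001% in the Rps1-c mock library, the next highest mock library having 0.476%. In the Rps3-c inoculated library, 26 nt reads were 3.201% and 30 nt reads 2.658%. The Rps3-a mock library had 129.9 RPM of miR398 and 27.2 of miR408, and the Rps3-a inoculated library had 18.59 of miR399. The Rps6 mock library was lowest in tasiARF (16.01 RPM), miR319 (5487) and miR160 (19.07). The response of 1 sequence of 23 nt differed between Williams and the 9 lines by -2.823 on the log2 scale. Reads over 30 nt, outside the sequences tested, were 43.79% of inoculated libraries against 29.9% of mock libraries. There were 193 sequences at 1 or more RPM in at least 5 inoculated libraries and at 0 in all mock libraries, and 0 the other way round.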

How the results depend on the processing

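Over 28 alternatives 921 values were recomputed, and 856 kept their direction and side of the threshold or stayed within 1.5 times. Division by the median family level, of all families or of the 27 of mean at least 10 RPM, leaving out rRNA pieces and leaving out Rps1-c and Rps3-a were added after the data were seen. Of 395 values of the 18 families named by the rule 370 were the same, 13 no longer passed (all after either division, but for miR408 with no replicate block and without Rps1-c and Rps3-a) and 12 reversed. These were miR1510 at 0.12 and miR408 at 0.18 after rescaling to 20 to 24 nt reads, and at 0.35 and 0.37 after division by the median family level. Relative to the median of the 27 families, miR1510 (0.67), miR1507 (0.31), miR156 (0.19), miR2109 (0.069), miR319 (0.065), miR403 (0.054), miR160 (0.053) and miR482 (0.013) reversed. Of all 33 families, 6 turned direction after that rescaling and 8 after division by the median of all. Of 85 list values 84 were the same, with adjusted p up to 7.925e-04, and the other list did not pass after rescaling to 20 to 24 nt reads (adjusted p = 0.110). Rescaling to 20 to 24 nt reads left 710 sequences that fell and gave 3 families that rose. Division by the median level of all gave 17 families, 6 that rose and 11 that fell, and by that of the 27 it gave 11, 8 that rose and 3 that fell, so these directions depend on which families set the level. A mean of at least 5 RPM gave 6421 changed sequences (3022 rose, 3399 fell) and 50 gave 722 (439 and 283), as more or fewer were tested. As a percent of 20 to 24 nt reads, 3 length classes passed, the 22 nt difference reversed to 0.408 and the 23 nt class passed (3.58). By distinct sequences the 23 nt difference reversed to -0.332 and the 25 nt class did not pass (0.0819). The cause was not tested.

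Sequences that differed between lines numbered 13 and 2 with means of 5 and 50, 3 by edgeR, and 2 without Rps1-c and Rps3-a, which left 1 family. The Williams response gave 0 sequences with a pseudocount of 0.5, either rescaling or a mean of 5 or 50. With each line left out, changed sequences numbered 3543 to 3569, families 31 to 31, lists 5 to 5, length classes 12 to 12, sequences differing between lines 2 to 8, families 1 to 4, and the Williams response and level 0 to 1 and 0 to 0 sequences. With no replicate block, 3574 sequences, 30 families, 5 lists and 12 length classes passed, within 3 of the numbers with the block. The alternatives for reads over NB-LRR genes and for phased loci were not run, for lack of a genome. Depth differed between treatments without overlap, and 1 library per line limits the line and Williams tests.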

Other observations

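The test of deals without the sequences of the 2 libraries, like the division by the median family, was chosen after the result was seen. Some 21 to 24 nt sequences were near absent from both libraries of some lines and present in both of the others, named here after their values were seen. TCGAGATCAATGGAAGGCTTT and TTGAGGATTACTCTGTTGAGA were at most 0.38 and 0.25 RPM in Rps3-a and at least 2.85 and 3.2 in the other lines. CCAGGATGTAGACCCCTATAGGCC was at 0 in Rps1-a and at least 2.28 in the other lines, and CTGAACTCCATGGATCTGAGAA was at 7.24 to 22.99 RPM in Rps1-k and at 0 in the other lines.

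A hypothesis was that such sequences follow the line. With the inoculated libraries dealt out at random to the lines, 16 of 100 deals, the real one included, gave as many as the 4 of the real pairing (highest other 100), so this planned test did not exclude chance. Of these deals 15 gave the Rps1-c mock library the Rps3-a inoculated library, which share the sequences described above. A second test left out those sequences and also all others with nearly all of their RPM in these 2 libraries. The real pairing still gave 4, and 1 of 100 deals gave as many (highest other 3). What was left out counted mainly in deals that join these 2 libraries, so the filter itself lowered the other deals. The result may reflect the lines, but it cannot exclude chance. It rests on 4 sequences and a test chosen after the first had failed.

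The 193 sequences found in inoculated libraries alone summed to 382 ± 44.1 (SD, n = 10) RPM. Their median length was 42 nt, 144 were over 30 nt and 18 were of 20 to 24 nt. Of these sequences 89.1% shared 16 nt with a sequence listed in all mock libraries.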
